A study of Mus musculus with 36 samples.

How the data were processed

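The study measured RNA from primary cortical neuron cultures of embryonic (E15) CD1 mouse pups, an outbred strain. Per the labels' protocols, neurons were plated for 24 h and then treated for 6 h, total RNA was isolated with the miRNeasy kit, the Ribo-Zero Gold kit served to deplete ribosomal RNA, and libraries were sequenced on an Illumina HiSeq instrument. The 36 libraries form 6 groups of 6: untreated control, sodium selenite at 0.1, sodium selenite at 1, HCA, HCA with selenite at 0.1, and HCA with selenite at 1. The sample labels give the selenite doses in mM, while the series text gives the same range in micromolar, so the doses are written here without a unit. HCA was given at 5 mM. The sample labels spell it out as homocysteic acid, a glutamate analogue known to block cystine uptake and deplete glutathione, whereas the series text calls HCA a ferroptosis inhibitor. The labels number 6 culture batches, and each batch holds 1 library of every group, so the replicate numbers pair the libraries across groups.

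The authors' deposited table holds estimated counts, although its name speaks of TPM. Its 36 columns sum to between 34.3 M and 56.9 M counts, not to a common total, and from 7.97% to 58.8% of a column's values are whole within 1e-06. STAR, Salmon and the GRCm38 build are named in the submitters' processing notes without versions or settings, and the annotation release is not given in the sources used here. The file name speaks of filtering, and the filter is not given in the sources used here. Because the plan written before the data were examined named edgeR's quasi-likelihood test for a table of counts, that test replaced the planned test of log2 TPM values. The estimated counts were rounded to whole numbers first.

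The row identifiers are Ensembl gene identifiers, and 27094 of the 27288 (99.29%) occur in GENCODE vM21 on GRCm38. The values under them, however, appeared to go with other genes. The row of the tRNA mt-Tl1 had a median of 1090260 counts, that of Fthl17f 143709 and that of the tRNA mt-Ts1 35019, and the transcripts just before theirs in identifier order belong to mt-Rnr2, Tuba1a and mt-Co1. Before transcript identifiers, 5 other orders were tried (gene identifier, start, end, start among coding genes, and annotation file order). Each row was therefore compared with the transcripts that stand near those of its own gene when the 141862 transcripts are sorted by transcript identifier, at shifts of -6 to 6 transcripts, using the 9796 identifiers with 1 annotated transcript. At a shift of -1, row totals separated coding transcripts other than receptors from the rest with an area under the curve of 0.746. It was 0.714 at no shift and 0.631 to 0.644 at the other shifts. Coding transcripts of odorant and pheromone receptors were counted with the rest, so this area is not independent of the receptor counts given next. At that shift 7 of these rows would hold an odorant or pheromone receptor transcript, against 97 at no shift and 161 to 181 at the others, and 31 would hold a ribosomal protein gene, against 0 at no shift and 11 to 17 at the others. At no shift only ribosomal protein genes with 1 annotated transcript could count, so the 0 there does not speak for the shift. The median log2 total count of the 31 was 12.9, against 8.39 to 12.3 at the other shifts, so this median separates the shifts little. A test written down beforehand came out against this reading: rows given to the same gene at a shift of -1 had a median correlation of 0.277 over libraries, below the highest value of 0.412 at another shift. A rule that voids this test where pairs of rows of different genes, matched on level, correlate as much (0.306) was written after that result. With 3 components removed, these values were -0.0748 and 0.0009, which went against what the test predicted as well. The test takes rows given to 1 gene to vary together. Such rows hold different transcripts of it, and whether these vary together was not examined.

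Gene names in the text rest on that inference from identifier order and not on names in the file. Each row was taken to hold the transcripts that stand immediately before those of its labelled gene, and a gene was named through a row only where all coding transcripts so assigned came from 1 gene. This gave 9555 rows and 7514 genes, of which 5775 were tested, each through its row of highest mean count; 4990 rows and 4084 genes remained with identifiers of 1 transcript. A row can hold only some of a gene's transcripts, and non-coding transcripts of other genes besides. The shift and the rule of 1 coding gene were set before any groups were compared. The choice of the row of highest mean count was made after the genes held by the rows that passed for HCA against control had been seen. The symbol that GENCODE gives the row's own identifier stands beside each gene named as the deposited symbol. Coordinates are those of the named gene on GRCm38 in GENCODE vM21, and counts of rows past the threshold do not depend on the naming.

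Rows at a CPM of 1 or more in at least 6 libraries were kept, 19604 in all. The test was edgeR 4.0.16 with TMM scaling, estimated dispersions and quasi-likelihood F tests in their default form, over all 36 libraries with 1 mean per group, in R 4.3.3. It was two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05 for the adjusted p. A standard error is the log2 fold change divided by the square root of F. The default form was chosen after the counts past the threshold had been seen under 9 fits: the non-legacy quasi-dispersion without and with the block and with robust variance, the default form, limma voom with library weights without and with the block, and 3 fits without the libraries far from the others. The non-legacy form stays as an alternative. The 9 planned comparisons were each treatment against control, each combination against HCA, the doses against each other without and with HCA, and the interaction of HCA with each dose. HCA with selenite against selenite alone, at both doses, was added after seeing the data because these 2 comparisons share no library with that of HCA and control. Normalised CPM are given as mean ± SD over the 6 libraries of a group, and values below 0 or above 0 in a fold change are on the log2 scale. The TMM factors ranged from 0.0281 in selenite 0.1 replicate 5 to 4.32 in HCA with selenite 1 replicate 6. In control they ranged from 0.0723 to 1.965 and in HCA from 0.355 to 4.225, so normalised CPM and fold changes rest on strong rescaling.

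Genes were named by a rule fixed before the data were examined: up to 10 per direction with the largest change among those past the threshold, with a mean of 1 CPM or more and the same sign in at least 5 of the 6 batches, filled from the fit with the batch as a block where fewer passed; up to 4 members per gene list; and Gpx4, Tfap2c and Sp1 always. No row could be given to Sp1. Other members of gene lists named in the text were chosen after their values had been seen. For 1 gene picked by this rule the result is not reported here, no other was named in its place, and the gene lists and counts of rows still include it. A further 27 gene lists were fixed beforehand, and the 24 with at least 3 tested members were tested with limma 3.58.1's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry.

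Libraries of a batch deviated together from their group means, with a mean correlation of 0.107 over 90 pairs, against -0.0179 over 450 pairs of different batches. Deviations from a group mean cancel over its libraries, so the second mean is tied to the first and is no separate baseline. Single pairs reached 0.506 within a batch and 0.556 between batches. The mean within a batch was 0.143, 0.130, 0.131, 0.0964, 0.137 and 0.0044 in batches 1 to 6. The pairing rests on the labels. No 2 libraries of a group were alike within sampling noise, since the lowest chi-square per degree of freedom was 20.8. Each culture batch is a separate culture per the labels, while how many litters they came from is not given in the sources used here.

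The tests were first run on simulated data with the real library sizes. For HCA against control the filter on low values kept 13527 simulated rows, 13382 of them unchanged, where 19604 real rows were tested. Of 100 rows changed by 2-fold 22% were recovered and of 100 changed by 4-fold 67%, with 6 unchanged rows past the threshold. For HCA with selenite 1 against HCA, 13428 rows were kept, 13291 of them unchanged. There the shares were 22% and 58%, again with 6. Changed rows were drawn before this filter, and those it removed count as missed. The shares are therefore lower than recovery among the rows tested. Rows holding ribosomal RNA type transcripts took from 1.70% to 88.6% of a library, which left 4.95 M to 52.6 M counts outside these 41 rows, so precision differs widely between libraries. These rows were chosen through the inferred shift, by a transcript annotated as ribosomal RNA or one of a gene on a separate list of ribosomal RNA loci. They were counted whole, although they can also hold coding transcripts. Their shares, the counts outside them, the thinning and depth as a covariate therefore rest on the same hypothesis and on that list.

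Alternatives named before the data were examined were the batch as a block, no filter, a filter at 5 CPM, median of ratios scaling, the compared groups alone, robust variance, library weights with limma voom, and leaving out each batch. Alternatives added after seeing the data were DESeq2 1.42.0, limma voom without weights or with weights and the block, the non-legacy quasi-dispersion, leaving out 3 libraries far from the others (control replicates 5 and 6 and selenite 0.1 replicate 5), leaving out ribosomal RNA type rows, depth as a covariate, thinning to equal counts outside ribosomal RNA type rows, and other ways of giving rows to genes. Shares of ribosomal RNA were compared with exact permutation tests in Python 3.11.15 with SciPy 1.17.1.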

Results

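The data were 36 RNA-seq libraries of mouse primary cortical neurons, from 6 culture batches under each of 6 conditions. The conditions crossed sodium selenite, a source of selenium for selenoproteins, at 0, 0.1 or 1 with and without 5 mM homocysteic acid (HCA), a glutamate analogue that blocks cystine uptake. Estimated counts per library ranged from 34.3 to 56.9 M. Rows holding ribosomal RNA type transcripts took 76.2% ± 15.2 (SD, n = 6) of the counts in control, 58.5% ± 29.6 in selenite 0.1, 37.4% ± 30.4 in selenite 1, 45.7% ± 30.0 in HCA, 55.8% ± 21.1 in HCA with selenite 0.1 and 33.4% ± 27.4 in HCA with selenite 1. These rows were chosen through the inferred shift of row identifiers set out below, by annotated type or a separate list of ribosomal RNA loci. The shares therefore rest on that hypothesis and that list. Selenite 1 had a lower share than control in 6 of 6 batches (two-sided exact permutation p = 0.0173, within batches 0.0312), which did not pass adjustment over 7 comparisons (adjusted exact p = 0.121 and 0.219). With 6 batches, 0.0312 is the lowest p the test within batches can give. A single comparison at that value could not pass the adjustment, so its failure there decides nothing. For HCA and control the exact permutation p was 0.0584 (adjusted 0.204, within batches 0.125, lower in 5 of 6 batches). HCA with selenite and selenite alone differed by -2.67 percentage points at dose 0.1 (exact permutation p = 0.866) and -4.02 at dose 1 (exact permutation p = 0.809). Counts outside these rows ranged from 4.95 M in selenite 0.1 replicate 5 to 52.6 M in HCA with selenite 1 replicate 6. Control libraries had 10.7 ± 7.30 M (SD, n = 6) and HCA libraries 23.1 ± 16.1 M, so counting error was larger in the controls.

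**Figure D1:**
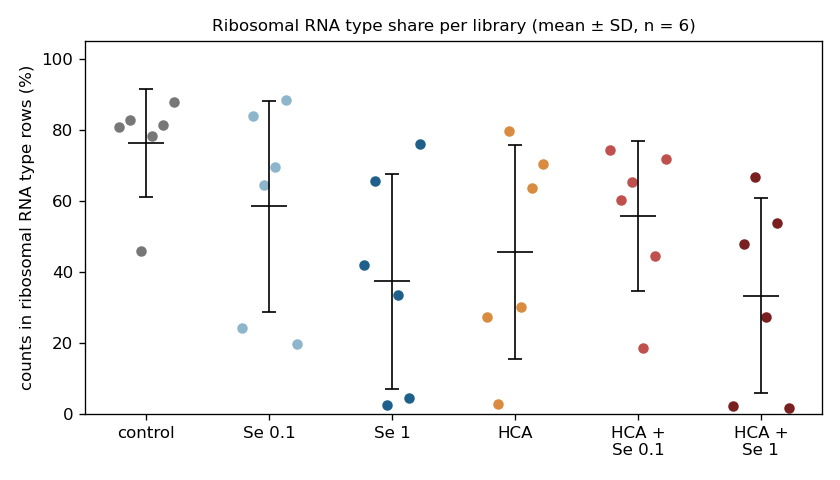
Percentage of each library's counts in rows holding ribosomal RNA type transcripts, by group, 1 point per culture batch, with the mean ± SD (n = 6). The rows were chosen through the inferred shift in transcript identifier order, by annotated type or a separate list of ribosomal RNA loci. Control had a mean of 76.2% and HCA with selenite 1 a mean of 33.4%.

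Levels in the table appeared to go with genes 1 place away from the row identifiers in transcript identifier order, which stays a hypothesis. The row of the mitochondrial tRNA mt-Ts1 had a median of 35019 counts per library, and the transcript just before it belongs to the cytochrome c oxidase subunit mt-Co1. The row of the tRNA mt-Tl1 had 1090260 and is preceded by mt-Rnr2, the large mitochondrial ribosomal RNA, and the row of Fthl17f had 143709 and is preceded by the tubulin gene Tuba1a. Genes are named below through this shift, with the symbol of the deposited identifier in parentheses, and each name is an inference from identifier order. With symbols as deposited, 0 gene lists passed limma's camera for HCA against control, against 5 with the shifted names.

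**Figure D2:**
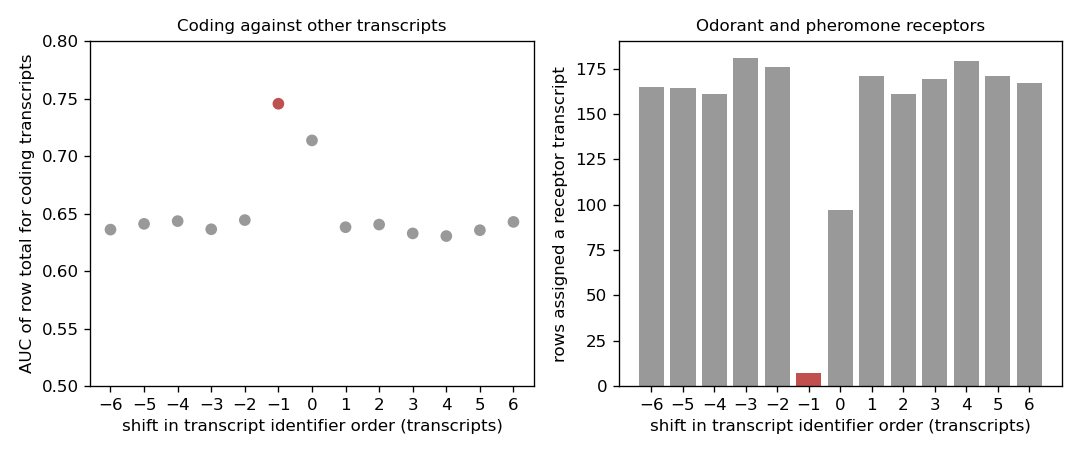
Left, area under the curve with which a row's total count separates coding from other transcripts, by the shift in transcript identifier order, over 9796 identifiers with 1 transcript. Coding transcripts of odorant and pheromone receptors were counted with the other transcripts. Right, number of those rows that would hold an odorant or pheromone receptor transcript, which was 7 at a shift of -1, where the area was 0.746.

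HCA against control asks what the glutamate analogue changes in these neurons after 6 h. Targets of the transcription factor Atf4 in the integrated stress response, which acts when amino acids run short, were higher as a list. Cars, the cysteinyl-tRNA synthetase, rose by 1.40 ± 0.13 (log2, SE, n = 6 and 6; Cd164l2, edgeR adjusted p = 1.1e-08), from 11.6 ± 3.15 to 30.9 ± 3.33 CPM, and was higher in 6 of 6 batches. The secreted glycoprotein gene Stc2 rose by 1.97 ± 0.29 (Vmn2r81), Eif4ebp1, a repressor of cap-dependent translation, by 1.39 ± 0.23 (Chrna6) and the alanyl-tRNA synthetase Aars by 0.94 ± 0.14 (Cdh15). Slc3a2, the heavy chain shared by cystine and large neutral amino acid transporters, rose by 0.63 ± 0.11 (Nxf1, adjusted p = 0.0022). Genes induced by neuronal activity also rose: the transcription factor Nr4a1 by 3.15 ± 0.50 (Krt88, adjusted p = 5.1e-04), the clock gene Per1 by 2.95 ± 0.61 (Vamp2, adjusted p = 0.0161) and the AP-1 subunit Fosl2 by 1.43 ± 0.32 (Rbks, adjusted p = 0.0298), each higher in 6 of 6 batches. The call of Per1 was lost without batch 1, 4 or 5 (adjusted p = 0.146, 0.178 and 0.0940), and that of Fosl2 without any batch but batch 3 (0.0689 to 0.178). Limma voom ended the calls of Nr4a1, Per1 and Fosl2. Leaving out the 3 libraries far from the others ended those of Per1 and Fosl2. Ccdc184 (1.44 ± 0.22, 2210010C04Rik) and Banp (0.95 ± 0.21, Taf1c) rose as well, Banp losing its call without any batch but batch 5 (0.0549 to 0.266). Mc4r, the melanocortin 4 receptor, was lower at -1.48 ± 0.28 (Ugt8a, 1.85 ± 0.728 to 0.677 ± 0.0880 CPM, 5 of 6 batches, adjusted p = 0.0041), and not past the threshold without batch 1 (0.0568) or 3 (0.0579).

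Of 13 tested members of the Atf4 list, 6 rose over all genes tested and 10 adjusted over the list alone, with a median of 0.90 (camera adjusted p = 2.8e-28, 1.5e-06 as adjusted p with an estimated correlation, fry adjusted p = 1.3e-09). Shmt2, a mitochondrial serine hydroxymethyltransferase (1.03 ± 0.24, Inhbc), passed with the culture batch as a block (adjusted p = 0.0128) and not without it (0.0505), and Atf5 stood at -0.14 ± 0.26. Of 14 immediate early and activity genes, 4 rose over all genes and 6 adjusted over the list alone, with a median of 0.89 (camera adjusted p = 2.3e-08, 3.3e-04 as adjusted p with an estimated correlation, fry adjusted p = 1.9e-06), while Arc stood at -0.25 ± 0.62 and Egr2 at 0.18 ± 0.25. The list of genes that protect from ferroptosis, an iron-dependent death by lipid peroxidation, was higher in camera (8 members, 1 risen over all genes and 3 adjusted over the list alone, camera adjusted p = 0.0021, fry adjusted p = 0.0039). With an estimated correlation its adjusted p was 0.0841, and 0.0203 with the batch as a block. Over the 46 rows that hold any coding transcript of a member, the call was lost, with a median of 0.16 (camera adjusted p = 0.328). Its median was 0.56 and its mean 0.14, the member that rose over all genes was Slc3a2, also in the Atf4 list, and Vkorc1l1 stood at -2.98 ± 1.56. Mitochondrially encoded genes were lower in camera (12 members, median -0.50, adjusted p = 2.8e-04), a call lost with an estimated correlation (adjusted p = 0.277), with depth as a covariate (0.0522) and, with the batch as a block, without the 3 distant libraries (0.254), and not made by fry (0.204). Over the list alone 1 member passed, mt-Nd6 at -1.01 ± 0.32, and the ribosomal RNA share also differed between these groups, at 45.7% against 76.2%. The astrocyte markers Slc1a3 (-0.64 ± 0.30), Slc1a2 (-0.52 ± 0.22) and Aldoc (-0.48 ± 0.47) were lower as a list (camera adjusted p = 0.0087, adjusted p = 0.0841 with an estimated correlation, fry adjusted p = 0.0317), with none past the threshold over the list alone. Over the 29 rows that hold any coding transcript of an astrocyte gene, the call was lost, with a median of -0.03 (camera adjusted p = 0.268).

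In all, 60 of 19604 rows passed edgeR's threshold, 50 higher and 10 lower, of which 16 and 2 were the row used for a named coding gene. Veph1 (Ptx3) was the row with -9.08 ± 1.62, and that row also holds a ribosomal RNA type transcript, so the value cannot be given to Veph1. Control libraries ranged from 0 to 1156 CPM in it and HCA libraries from 0.236 to 0.606. With the batch as a block 87 rows passed (69 higher, 18 lower), 58 of them in both fits. The block added Olig2, a marker of oligodendrocyte precursors (-0.85 ± 0.19, adjusted p = 0.0342 against 0.225), the phosphodiesterase Pde1b (-0.91 ± 0.21), the kinesin Kif2c (-0.65 ± 0.12), the lysosomal channel Tpcn1 (-0.90 ± 0.20), Wscd1 (-0.78 ± 0.18) and the metal exporter Slc30a10 (-1.19 ± 0.28) as lower, and the selenoprotein gene Selenoo (Gm24966) as higher (0.77 ± 0.18, adjusted p = 0.0454 against 0.181). Rows that hold coding transcripts of several genes cannot be given to any of them. Those named next were chosen after their values were seen, and each holds a member of the Atf4 or activity list. They are the row of Atf4, Npr2 and Pcsk1 (1.44 ± 0.13, Rhobtb3, adjusted p = 6.6e-09), that of Asns, Adipoq and Dap3 (1.43 ± 0.15, Dlx6), that of Slc7a5 and Zfp637 (1.34 ± 0.14, Slc19a3) and that of Pck2 and Impg1 (1.84 ± 0.22, Trem1). Those of Mthfd2 and Tctex1d4 (1.18 ± 0.14, Kit), Chac1 and Zbtb20 (1.51 ± 0.24, Atrn), Trib3 and Sult4a1 (2.22 ± 0.49, Bcdin3d) and Fos and Bfsp2 (2.49 ± 0.52, Erg28) also passed. Rows of several genes without a member of any list passed too. Among them were the row of Gfm2, Tulp1 and Vmn2r9 (10.05 ± 1.68, Vmn2r107) and that of Hdc and Slc17a1 (4.02 ± 0.84, Usp8). Fitting the compared groups alone left 25 rows, DESeq2 gave 159, limma voom 34 and voom with library weights and the block 399, and leaving out batch 1 or batch 4 left 30 or 34. Without control replicates 5 and 6 and selenite 0.1 replicate 5, which lie far from the other libraries, 70 passed.

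**Figure D3:**
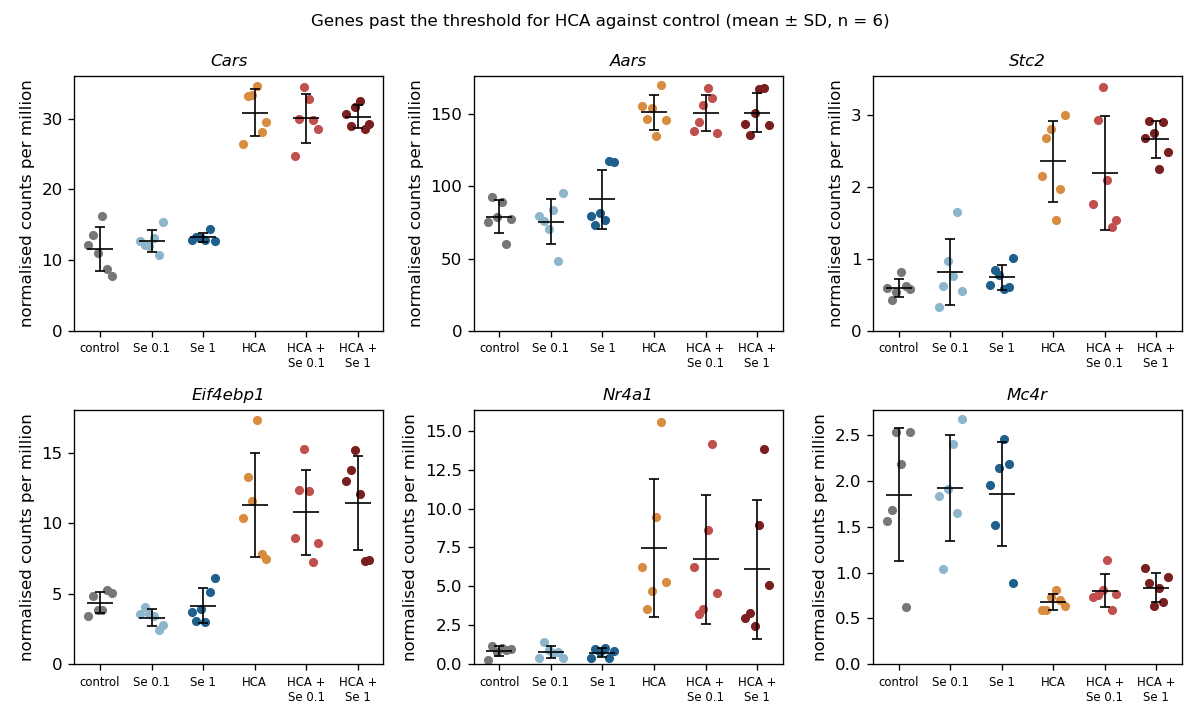
Normalised CPM of 6 genes that passed the threshold for HCA against control, by group, 1 point per culture batch, with the mean ± SD (n = 6). Cars had a mean of 11.6 CPM in control and 30.9 in HCA, and Mc4r 1.85 and 0.677.

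HCA with selenite against selenite alone, compared after seeing the data, asks whether the response to HCA is present in other libraries of the same 6 culture batches. At dose 0.1, Nr4a1 rose by 3.22 ± 0.50, Eif4ebp1 by 1.67 ± 0.23, Stc2 by 1.66 ± 0.28, Cars by 1.22 ± 0.13, Aars by 0.99 ± 0.14 and Slc3a2 by 0.84 ± 0.11 (n = 6 and 6, edgeR adjusted p from 1.1e-07 to 0.0012, higher in at least 5 of 6 batches). Aldh18a1, a proline synthesis enzyme, rose by 1.02 ± 0.20 (Tctn3), Shmt2 by 1.08 ± 0.24, Ttc17 by 1.87 ± 0.39 (Ccdc8) and Ccdc184 by 1.20 ± 0.22, while Mc4r was lower at -1.28 ± 0.27. Ccdc184 lost its call without batch 1 (adjusted p = 0.0762), and without single batches so did Shmt2 (up to 0.260, without batch 1), Mc4r (up to 0.215, without batch 1), Ttc17 (up to 0.114, without batch 6) and Aldh18a1 (up to 0.109, without batch 3). At dose 1, Nr4a1 rose by 3.02 ± 0.46, Stc2 by 1.86 ± 0.26, Eif4ebp1 by 1.47 ± 0.22, Cars by 1.20 ± 0.12, Ccdc184 by 1.18 ± 0.21, Slc3a2 by 0.73 ± 0.11 and the bZIP factor Nfil3 by 0.83 ± 0.15 (C330011M18Rik), each in 6 of 6 batches (edgeR adjusted p from 1.3e-07 to 0.004). Slc7a3, a cationic amino acid transporter, rose by 3.89 ± 0.82 (Olfr980) and the granin Scg2 by 2.56 ± 0.55 (Gm29320), and Cars2, the mitochondrial cysteinyl-tRNA synthetase (-1.23 ± 0.26, Prl3a1), and Wscd1 (-0.99 ± 0.20, Obox6) were lower. These 4 lost their calls without single batches (adjusted p up to 0.371 for Slc7a3 without batch 1, 0.186 for Scg2 without batch 1, 0.158 for Cars2 without batch 3 and 0.512 for Wscd1 without batch 6), as did Nfil3 without batch 4 (0.0586).

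The Atf4 list was higher at both doses, with medians of 0.99 (8 of 13 risen over all genes, 10 adjusted over the list alone, camera adjusted p = 9.2e-38) and 0.73 (7 risen, 10 adjusted over the list alone, camera adjusted p = 5.7e-43). With an estimated correlation these adjusted p were 1.9e-07 and 1.5e-08, and by fry 1.3e-09 and 5.0e-10. Immediate early and activity genes had medians of 0.66 and 0.62 (2 of 14 risen at each dose, 4 adjusted over the list alone, camera adjusted p = 6.5e-07 and 1.4e-10, 0.0016 and 6.7e-05 as adjusted p with an estimated correlation, fry adjusted p = 7.3e-05 and 2.0e-05). Fosl2 passed with the batch as a block alone, at 1.34 ± 0.24 (adjusted p = 0.0032 against 0.0729) and 1.38 ± 0.23 (0.0015 against 0.0531). Cholesterol synthesis genes, targets of SREBP2, were higher at both doses, with medians of 0.65 and 0.64 (camera adjusted p = 0.0025 and 4.8e-04, 0.0064 and 0.0024 as adjusted p with an estimated correlation, fry adjusted p = 2.9e-04 and 9.5e-04). None of its 8 members passed over all genes, while 2 and 1 did adjusted over the list alone, among them Fdps, farnesyl diphosphate synthase (2.00 ± 0.51 and 1.51 ± 0.49). With identifiers of 1 transcript alone, the call at dose 0.1 was lost (0.0662). Astrocyte markers were lower at dose 1 (median -0.78, camera adjusted p = 3.1e-04, adjusted p = 0.0064 with an estimated correlation, fry adjusted p = 0.0025), with 2 members, Slc1a3 (-0.78 ± 0.30) and Slc1a2 (-0.60 ± 0.21), past the threshold adjusted over the list alone. At dose 0.1 their list had a median of -0.46 (camera adjusted p = 0.103), which passed without batch 5 (0.0035) and without the 3 distant libraries (0.0246, and 0.002 with the block as well). Over the 29 rows that hold any coding transcript of an astrocyte gene, the median at dose 1 was -0.04 and the call was lost (0.323). Ferroptosis protecting genes passed camera at both doses (adjusted p = 0.0072 and 0.0177, fry adjusted p = 0.0229 and 0.0829), lost with an estimated correlation (adjusted p = 0.153 and 0.150, and 0.0291 at dose 0.1 with the block). Its median at dose 0.1 was 0.30 and its mean -0.13, while at dose 1 they were 0.08 and 0.08. At dose 1 the call was lost without batch 2 (0.0897) or 4 (0.205). With identifiers of 1 transcript alone, both calls were lost (3 members, 0.559 and 0.530). Mitochondrially encoded genes passed as lower at dose 0.1 (median -0.46, camera adjusted p = 0.0081, adjusted p = 0.549 with an estimated correlation, fry adjusted p = 0.417), which was lost without batch 2 (0.0973), batch 5 (0.593) or the 3 distant libraries (0.317). Metallothioneins and zinc exporters at dose 1 (median -0.71) passed camera with the batch as a block (adjusted p = 0.0228) and not without it (0.0590).

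In edgeR 42 rows passed at dose 0.1 (38 higher, 4 lower) and 43 at dose 1 (35 higher, 8 lower). With the batch as a block they were 68 (58 and 10) and 73 (47 and 26). At dose 0.1 the block added Selenoo (0.86 ± 0.18, adjusted p = 0.0216 against 0.119) and Peg12 (-0.63 ± 0.14, Mkrn3) and lost the row of Veph1 (0.0590 against 0.0255). At dose 1 it added the hedgehog effector Gli1 (-1.72 ± 0.34), the astrocytic membrane protein gene Mlc1 (-1.34 ± 0.26), S1pr1 (-0.92 ± 0.20), Sall3 (-0.82 ± 0.18), Pde1b (-1.11 ± 0.21), Tpcn1 (-0.91 ± 0.20) and Mc4r (-1.14 ± 0.26) as lower. The row of Veph1 stood at -6.90 ± 1.49 and -8.37 ± 1.55. The 50 rows higher in HCA against control shared 33 with the 38 at dose 0.1, where independent lists would share 0.0969, and 31 with the 35 at dose 1, where they would share 0.0893. In all 3 comparisons 33 rows passed, 30 of them higher in each, and 12 were the row used for a named gene. Limma voom gave 86 and 171 rows, DESeq2 130 and 117, and the compared groups alone 26 and 28. Leaving out batch 1 gave 27 and 25, leaving out batch 3 gave 27 at dose 1, and without the 3 distant libraries 70 and 70 passed.

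Selenite alone against control asks which transcripts selenium supply changes, and selenoproteins are the genes it is known to serve. Of 24 selenoprotein genes 9 were tested, with medians of 0.07 at dose 0.1 and 0.27 at dose 1 (camera adjusted p = 0.943 and 0.553, fry adjusted p = 0.974 and 0.737), and none passed. Gpx4, the glutathione peroxidase that removes lipid hydroperoxides, was at 0.25 ± 0.67 and 0.17 ± 0.65 (n = 6 and 6; Dio3), and its row, with 1 coding transcript of the gene, had 1.33 ± 1.39 CPM in control, 1.29 ± 0.796 in selenite 0.1 and 1.35 ± 1.03 in selenite 1. With these errors a change in Gpx4 is not excluded. All Gpx4 values here and below come from this row of low level, which may not stand for the gene as a whole. Tfap2c, a transcription factor known to be activated by selenium in neurons, was at -0.22 ± 0.72 and 0.70 ± 0.70 (Gcnt7). The selenophosphate synthetase gene Sephs2 was at 0.08 ± 0.15 and 0.20 ± 0.14, Selenoh at -0.04 ± 0.26 and 0.42 ± 0.25, Selenoo at -0.17 ± 0.24 and 0.27 ± 0.23 and Gpx1 at -0.56 ± 0.35 and -0.46 ± 0.34. Mitochondrially encoded genes passed camera as lower at dose 1 (median -0.44, adjusted p = 0.0032), with an adjusted p of 0.599 with an estimated correlation and 0.737 by fry. Over the list alone mt-Nd6 (-1.07 ± 0.32) passed, and Acsl4, an acyl-CoA synthetase known to promote ferroptosis (-1.63 ± 0.53), passed over the ferroptosis promoting list alone. The mitochondrial call was lost without batch 1 (0.126), 5 (0.276) or 6 (0.0793), without the 3 distant libraries (0.232) and with depth as a covariate (0.619), and the ribosomal RNA share was 37.4% in selenite 1 against 76.2% in control. By edgeR 0 rows passed at dose 0.1 and 0 at dose 1, with 799 and 912 under an unadjusted p of 0.05. DESeq2 gave 9 and 16, limma voom 0 and 0, voom with library weights 0 and 0, with weights and the block 1 and 2, edgeR's non-legacy form 1 and 1, and edgeR without batch 3 5 and 7.

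Selenite added to HCA, against HCA alone, asks whether selenium alters the state of neurons given the glutamate analogue. Cars was at 30.9 ± 3.33 CPM in HCA, 30.0 ± 3.43 with selenite 0.1 and 30.3 ± 1.62 with selenite 1 (SD, n = 6). Slc3a2 was at 55.2 ± 6.89, 58.9 ± 4.02 and 57.8 ± 3.05 CPM. Gpx4 was at -0.30 ± 0.62 for dose 0.1 and -0.39 ± 0.62 for dose 1, and Tfap2c at 0.08 ± 0.67 and 0.06 ± 0.67. The 9 selenoproteins had medians of -0.06 and -0.21 (camera adjusted p = 0.700 and 0.104, fry adjusted p = 0.950 and 0.885), and the list passed as lower at dose 1 without batch 3 (0.0447). Targets of NRF2, which directs glutathione synthesis, had a median of -0.20 at dose 0.1 and passed camera with the batch as a block (adjusted p = 0.0436, and 0.271 with an estimated correlation) and not without it (0.125). By edgeR 0 rows passed at dose 0.1 and 0 at dose 1, with 119 and 104 under an unadjusted p of 0.05. DESeq2 gave 1 and 2, and limma voom, voom with weights, voom with weights and the block, and edgeR's non-legacy form gave 0 at both doses.

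The doses against each other ask whether the response grows with selenite. Without HCA, selenoproteins had a median of 0.12 in dose 1 against dose 0.1 (camera adjusted p = 0.428), Gpx4 was at -0.08 ± 0.63 and Tfap2c at 0.92 ± 0.70. Mitochondrially encoded genes passed camera as lower (median -0.37, adjusted p = 0.0242, adjusted p = 0.683 with an estimated correlation, fry adjusted p = 0.549), which was lost without batch 2 (0.196), batch 5 (0.571) or the 3 distant libraries (0.418) and with depth as a covariate (0.275). With HCA, selenoproteins had a median of -0.09 (camera adjusted p = 0.488), Gpx4 was at -0.09 ± 0.62 and Tfap2c at -0.02 ± 0.67. By edgeR 0 rows passed without HCA and 0 with it, with 780 and 74 under an unadjusted p of 0.05. DESeq2 gave 0 and 4, limma voom and voom with weights 0 in each, voom with weights and the block 6 and 0, edgeR's non-legacy form 0 in each, and edgeR without batch 3 1 without HCA.

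The interaction terms ask whether selenite acts differently in the presence of HCA. Selenoproteins had medians of -0.09 at dose 0.1 and -0.36 at dose 1 (camera adjusted p = 0.998 and 0.151), Gpx4 was at -0.55 ± 0.91 and -0.56 ± 0.90 and Tfap2c at 0.30 ± 0.98 and -0.64 ± 0.97. Mitochondrially encoded genes passed camera at dose 1 (median 0.43, adjusted p = 0.0162, adjusted p = 0.850 with an estimated correlation, fry adjusted p = 0.872). The call was lost without batch 1 (0.463), 5 (0.627) or 6 (0.253), without the 3 distant libraries (0.805) and with depth as a covariate (0.433). By edgeR 0 rows passed at dose 0.1 and 0 at dose 1, with 378 and 349 under an unadjusted p of 0.05. DESeq2 gave 3 and 7, limma voom and voom with weights 0 at both doses, voom with weights and the block 2 and 1, and edgeR's non-legacy form 0 and 1.

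Responses to the treatments were also compared across rows, which are not independent replicates. The log2 fold changes of selenite 1 and of HCA against the same controls correlated with r = 0.785, where unchanged groups simulated against those controls gave 0.615, and their covariance was 0.534 against a simulated 0.208. Simulated rows were drawn independently, without variation common to the rows of a library. An excess over the simulated values can therefore not be read as a shared response. With the controls split 3 and 3, the mean r over 20 splits was 0.144 (0.0825 to 0.188). For selenite 0.1 and HCA r was 0.595 (simulated 0.523), the covariance 0.420 against 0.197, and r with split controls 0.0325. Selenite 0.1 and selenite 1 had an r of 0.621 (simulated 0.523), a covariance of 0.430 against 0.196 and an r of 0.0428 with split controls. For the doses added to HCA these were 0.543 (simulated 0.508), 0.115 against 0.132, and -0.106. With each response taken from 3 batches of its own, mean r was 0.153 (0.0610 to 0.263) for selenite 1 and HCA. It was 0.0648 (-0.0906 to 0.242) for selenite 0.1 and HCA and 0.0904 (-0.0945 to 0.268) for the selenite doses. For the doses added to HCA it was -0.0155 (-0.123 to 0.0847).

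Other gene lists did not pass camera for HCA against control. Selenoproteins had a median of 0.38 (camera adjusted p = 0.0827, adjusted p = 0.300 with an estimated correlation, fry adjusted p = 0.0777) and 0.14 and -0.16 for HCA with selenite against selenite (0.0819 and 0.865), with Selenoo past the threshold adjusted over the list alone for HCA (0.0119) and at dose 0.1 (0.0032). The selenoprotein list passed for HCA without batch 2 (0.0224) or 5 (0.0337) and at dose 0.1 without batch 6 (0.0393), and with libraries thinned to an equal count outside ribosomal RNA type rows for HCA (0.0329) and at dose 0.1 (0.0446). For HCA its median fell to 0.21 with depth as a covariate (0.285), 0.22 without the 3 distant libraries (0.355), 0.14 with the block as well (0.266) and 0.16 over the 47 rows that hold any coding transcript of a member (0.587), and without batch 4 its adjusted p was 0.241. At dose 0.1 the adjusted p rose to 0.218 without the 3 distant libraries and 0.379 without batch 5. Cholesterol synthesis genes had a median of 0.53 (0.0827, 0.149 as adjusted p with an estimated correlation, fry adjusted p = 0.0085) and passed without batch 2 (0.0224), without the 3 distant libraries (0.0331) and over the 57 rows that hold any coding transcript of a member (1.2e-04). Among ferroptosis promoting genes the iron transporter Slc11a2 (0.68 ± 0.21, and 0.69 ± 0.21 at dose 0.1) passed adjusted over the list alone (0.0197 and 0.0165), as did Gad1, the GABA synthesis enzyme, over its list (0.97 ± 0.27 for HCA and 0.99 ± 0.26 at dose 1), and Olig2 (-0.84 ± 0.25 and -0.72 ± 0.25). The medians for HCA against control, each with its camera adjusted p, the adjusted p with an estimated correlation and the fry adjusted p, are given next. Selenocysteine synthesis and selenium uptake had 0.11 (0.993, 0.994, 0.541) and ferroptosis promoting genes 0.14 (0.50039, 0.582, 0.146). The unfolded protein response of the endoplasmic reticulum had 0.06 (0.993, 0.994, 0.581) and NRF2 targets 0.29 (0.259, 0.464, 0.118). Metallothioneins and zinc exporters had -0.28 (0.192, 0.277, 0.146) and heat shock genes 0.05 (0.976, 0.994, 0.438). P53 targets had 0.05 (0.442, 0.475, 0.105) and hypoxia and glycolysis 0.12 (0.741, 0.956, 0.418). Nuclear oxidative phosphorylation genes had 0.10 (0.993, 0.994, 0.643) and cytosolic ribosomal proteins 0.21 (0.717, 0.956, 0.481). Inflammatory NF-kB targets had 0.21 (0.976, 0.994, 0.480) and neuron and synapse genes 0.20 (0.976, 0.994, 0.480). Inhibitory neuron genes had -0.00 (0.741, 0.956, 0.481) and microglia -0.06 (0.442, 0.616, 0.581). The oligodendrocyte lineage had -0.38 (0.192, 0.288, 0.246) and radial glia and dividing cells -0.24 (0.993, 0.994, 0.696). Erythroid genes had -0.70 (0.0827, 0.288, 0.233). Median, mean and camera direction differed in sign for selenocysteine synthesis and uptake (mean 0.13, lower in camera), the unfolded protein response (mean 0.00, lower in camera), heat shock genes (mean -0.02, higher), nuclear oxidative phosphorylation (mean -0.12, lower) and inhibitory neuron genes (mean 0.11, higher). Too few members could be tested for transcription factors of the TFAP2 and SP families (Tfap2d -0.15 ± 0.33, Tfap2c 0.18 ± 0.70), endothelial and mural cells (Pecam1 -0.61 ± 0.67) and meningeal fibroblasts (Col3a1 0.37 ± 0.96, Col1a2 0.59 ± 1.36).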

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

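Tests of receptor transcripts and of Atf4 genes by shift, the voiding of the correlation test and the 2 comparisons of HCA with selenite against selenite were chosen after results had been seen, and the rise of Atf4 genes had been noticed before the tests of its causes were written.

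The levels appeared not to go with the row identifiers, and a shift of 1 transcript in identifier order is a candidate explanation. It was found on these data, after 5 other orders had been tried, so it stays a hypothesis. At a shift of -1 the number of rows that would hold a receptor transcript was 7, against at least 97 at the others, and 20 of the 60 rows past the threshold for HCA would hold a coding transcript of the Atf4 list, against at most 1. A test written beforehand went the other way: rows given to 1 gene correlated at a median of 0.277 at this shift and up to 0.412 at another. Rows of different genes matched on level correlate as much (0.306), so its bound could not separate them, which was looked at only after it had failed. With 3 components removed, matched rows were at 0.0009 and rows given to 1 gene at -0.0748, the lowest of all shifts. This again goes against what the test predicted under the shift and is left unexplained. Rows given to 1 gene hold different transcripts of it, and whether these vary together was not examined. The correlation does not support the shift.

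Atf4 genes were higher in HCA than in control. With every library thinned to an equal count outside ribosomal RNA type rows their median stayed at 0.88, and without the 3 distant libraries at 0.85, which argues against depth outside these rows and against these libraries as the whole cause. In the libraries of HCA with selenite and selenite alone, which share none with this comparison but come from the same culture batches, the lower of the medians was 0.73. A response to HCA may therefore underlie it, as a hypothesis that rests on the inferred gene names. The thinning rests on ribosomal RNA type rows chosen through the same inference.

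Other splits of the same libraries were counted, 60 per comparison with the real one. For HCA against control 1 split, the real one, gave as many as 60 rows and the highest other gave 3, and within batches 1 of 24 gave as many as 87, with 2 as the highest other. All 32 swaps within batches had been seen before these 24 were drawn. For HCA with selenite 0.1 against selenite 0.1 it was 1, with 42 rows against at most 6. Over 60 splits chance is therefore unlikely in both comparisons, though not excluded. The count within batches gives no separate test, since its swaps had been seen. For HCA with selenite 1 against selenite 1 chance stays open by this count: 3 of the 60 splits gave at least the real 43, and the highest gave 3157. What the splits calling that many have in common was not examined. The highest parted 2 batches where the real one parts 6, and with the batch as a block 73 passed. Of the 43 rows, 31 of the 35 higher rows and 4 of the 8 lower ones also passed in the same direction for HCA against control, which shares no library with it, where independent lists would share 0.0893 and 0.00408. That expectation takes every row as equally likely to pass. Both comparisons use row variances from 1 fit and the same culture batches, so the lists are not independent. So large an overlap in the same direction argues against chance alone for the rows shared, without being a test. By the count of splits chance stays open for the others. Where the real split gave 0 rows, every split gives as many by design, so the count decides nothing about chance. There 60 of 60 gave as many for selenite 0.1 and selenite 1 against control, with highest others of 137 and 249, which were not examined further. The same 60 held for HCA with selenite 0.1 and 1 against HCA (1 and 0), the doses without and with HCA (1 and 0) and the interactions (1 and 3).

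A single library lay apart from its group, by the gap to its neighbour over the whole range, in 12 of 138 groups. Chance flags about 1 in 20 groups. Control replicate 3 had 45.8% ribosomal RNA against a median of 81.2% (0.774) and 25.5 M counts outside it against 7.87 M (0.916). In log2 CPM, Gpx4 was at -5.20 in control replicate 6 (0.667), selenite 0.1 replicate 5 (0.734) and selenite 1 replicate 6 (0.716), the floor of the scale. Tfap2c was at -5.20 in selenite 0.1 replicate 5 (0.705) and -2.64 in HCA replicate 3 (0.783), and Scg2 at -3.40 in selenite 1 replicate 6 (0.735). Control replicate 5 stood apart for Mc4r (-0.63, 0.653) and Wscd1 (4.85, 0.794), control replicate 1 for Nr4a1 (-1.63, 0.704) and selenite 1 replicate 5 for Cars (3.86, 0.647).

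The interaction of HCA and selenite 1 passed camera for mitochondrially encoded genes (adjusted p = 0.0162). The call was lost with an estimated correlation (adjusted p = 0.850), by fry (0.872), without batch 1, 5 or 6 (0.463, 0.627 and 0.253) and without the 3 distant libraries (0.805), so a difference is not established.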

How the results depend on the processing

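Tools other than edgeR's default form, the settings without 3 libraries, without ribosomal RNA, with depth and with thinning, and the other ways of naming rows were chosen after the data had been seen. Of 817 values of named genes past the threshold, 717 stayed past it, 100 did not, and 0 turned sign. Fitting the compared groups alone ended 15 of these calls: Per1, Fosl2, Banp and Slc3a2 for HCA against control, Ttc17, Stc2, Shmt2, Aldh18a1 and Mc4r at dose 0.1, and Slc7a3, Scg2, Ccdc184, Nfil3, Cars2 and Wscd1 at dose 1. Limma voom ended 6 (Nr4a1, Per1 and Fosl2 for HCA against control, and the row of Veph1 in all 3) and library weights 6 (Per1, Fosl2 and Banp, and the row of Veph1 in all 3). Depth as a covariate ended 4 (Fosl2 and Banp, and at dose 0.1 Shmt2 and the row of Veph1). The non-legacy form ended Ttc17 at dose 0.1 and Scg2 at dose 1, thinning Mc4r for HCA against control and at dose 0.1, and leaving out the 3 distant libraries Per1 and Fosl2. At dose 0.1 the filter at 5 CPM and median of ratios scaling each ended Shmt2, no filter Mc4r, and the block, without and with depth, the row of Veph1. The calls of Cars, Aars, Stc2, Eif4ebp1 and Ccdc184 for HCA against control held without each batch. All gene names depend on the inferred shift: with symbols as deposited the Atf4 and activity lists passed in none of the comparisons. The batch as a block changed no other call of the named genes and lists than those printed with it. The pseudocount and quantile alternatives belong to a test of log values and were not run. Correlations of responses with the shared libraries split by batch were 0.0904 (selenite 0.1 against control and selenite 1 against control) and -0.0155 (HCA with selenite 0.1 against HCA and HCA with selenite 1 against HCA).

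Apart from the ranges without each batch, only counts of rows and lists that moved from the main count beyond a fixed ratio, or to or from 0, are printed here. Of 17 alternatives for counts of rows, 12 stayed within that bound for HCA against control. For HCA with selenite against selenite alone 8 of 17 did so at each dose. Counts of rows past the threshold were, under DESeq2, 9 (selenite 0.1 against control), 16 (selenite 1 against control), 159 (HCA against control), 1 (HCA with selenite 0.1 against HCA), 2 (HCA with selenite 1 against HCA), 4 (HCA with selenite 1 against HCA with selenite 0.1), 3 (interaction of HCA and selenite 0.1), 7 (interaction of HCA and selenite 1), 130 (HCA with selenite 0.1 against selenite 0.1), 117 (HCA with selenite 1 against selenite 1). Under library weights (limma voom) with replicate block, 1 (selenite 0.1 against control), 2 (selenite 1 against control), 399 (HCA against control), 6 (selenite 1 against selenite 0.1), 2 (interaction of HCA and selenite 0.1), 1 (interaction of HCA and selenite 1), 1178 (HCA with selenite 0.1 against selenite 0.1), 918 (HCA with selenite 1 against selenite 1). Under edgeR non-legacy quasi-dispersion, 1 (selenite 0.1 against control), 1 (selenite 1 against control), 1 (interaction of HCA and selenite 1). Under libraries of the compared groups alone, 25 (HCA against control), 26 (HCA with selenite 0.1 against selenite 0.1), 28 (HCA with selenite 1 against selenite 1). Under limma voom, 34 (HCA against control), 86 (HCA with selenite 0.1 against selenite 0.1), 171 (HCA with selenite 1 against selenite 1). Under without 3 libraries far from the others, with replicate block, 118 (HCA against control), 121 (HCA with selenite 0.1 against selenite 0.1), 180 (HCA with selenite 1 against selenite 1). Under with replicate block, 68 (HCA with selenite 0.1 against selenite 0.1), 73 (HCA with selenite 1 against selenite 1). Under library weights (limma voom), 145 (HCA with selenite 0.1 against selenite 0.1), 216 (HCA with selenite 1 against selenite 1). Under without 3 libraries far from the others, 70 (HCA with selenite 0.1 against selenite 0.1), 70 (HCA with selenite 1 against selenite 1). Under depth as a covariate, with replicate block, 67 (HCA with selenite 0.1 against selenite 0.1), 70 (HCA with selenite 1 against selenite 1). Without each batch in turn they ranged from 0 to 5 (selenite 0.1 against control), from 0 to 7 (selenite 1 against control), from 30 to 59 (HCA against control), from 0 to 0 (HCA with selenite 0.1 against HCA), from 0 to 0 (HCA with selenite 1 against HCA), from 0 to 1 (selenite 1 against selenite 0.1), from 0 to 0 (HCA with selenite 1 against HCA with selenite 0.1), from 0 to 0 (interaction of HCA and selenite 0.1), from 0 to 0 (interaction of HCA and selenite 1), from 27 to 49 (HCA with selenite 0.1 against selenite 0.1), from 25 to 46 (HCA with selenite 1 against selenite 1). Counts of gene lists past camera were, under without 3 libraries far from the others, 0 (selenite 1 against control), 0 (selenite 1 against selenite 0.1), 0 (interaction of HCA and selenite 1). Under without 3 libraries far from the others, with replicate block, 0 (selenite 1 against control), 0 (selenite 1 against selenite 0.1), 0 (interaction of HCA and selenite 1). Under depth as a covariate, 0 (selenite 1 against control), 0 (selenite 1 against selenite 0.1), 0 (interaction of HCA and selenite 1). Under depth as a covariate, with replicate block, 0 (selenite 1 against control), 1 (HCA with selenite 0.1 against HCA), 0 (selenite 1 against selenite 0.1), 0 (interaction of HCA and selenite 1). Under symbols as deposited, 0 (selenite 1 against control), 0 (HCA against control), 0 (selenite 1 against selenite 0.1), 0 (interaction of HCA and selenite 1), 0 (HCA with selenite 0.1 against selenite 0.1), 0 (HCA with selenite 1 against selenite 1). Under with replicate block, 1 (HCA with selenite 0.1 against HCA). Under rows holding any coding transcript of a member, 2 (HCA with selenite 1 against HCA), 2 (selenite 1 against selenite 0.1). Under labels with 1 transcript alone, 3 (HCA with selenite 0.1 against selenite 0.1), 3 (HCA with selenite 1 against selenite 1). Without each batch in turn they ranged from 0 to 0 (selenite 0.1 against control), from 0 to 2 (selenite 1 against control), from 5 to 7 (HCA against control), from 0 to 1 (HCA with selenite 0.1 against HCA), from 0 to 2 (HCA with selenite 1 against HCA), from 0 to 1 (selenite 1 against selenite 0.1), from 0 to 0 (HCA with selenite 1 against HCA with selenite 0.1), from 0 to 0 (interaction of HCA and selenite 0.1), from 0 to 1 (interaction of HCA and selenite 1), from 4 to 6 (HCA with selenite 0.1 against selenite 0.1), from 5 to 6 (HCA with selenite 1 against selenite 1). Uncalled values turned sign under depth as a covariate, -0.14 (Gpx4, selenite 0.1 against control), -0.50 (Gpx4, selenite 1 against control). Under library weights (limma voom), 0.95 (Tfap2c, selenite 0.1 against control), -0.0539 (Tfap2c, HCA with selenite 0.1 against HCA), -1.06e-05 (Tfap2c, HCA with selenite 1 against HCA), 0.0539 (Tfap2c, HCA with selenite 1 against HCA with selenite 0.1), -1.005 (Tfap2c, interaction of HCA and selenite 0.1), -0.44 (Gpx4, HCA with selenite 0.1 against selenite 0.1), -0.26 (Gpx4, HCA with selenite 1 against selenite 1), 0.0127 (Tfap2c, HCA with selenite 1 against selenite 1). Under limma voom, 0.97 (Tfap2c, selenite 0.1 against control), -0.0172 (Tfap2c, HCA with selenite 1 against HCA), -0.91 (Tfap2c, interaction of HCA and selenite 0.1), -0.29 (Gpx4, HCA with selenite 0.1 against selenite 0.1), -0.0779 (Gpx4, HCA with selenite 1 against selenite 1). Under library weights (limma voom) with replicate block, 0.54 (Tfap2c, selenite 0.1 against control), -0.0832 (Tfap2c, HCA with selenite 1 against HCA), -0.53 (Tfap2c, interaction of HCA and selenite 0.1), -0.30 (Gpx4, HCA with selenite 0.1 against selenite 0.1), -0.22 (Gpx4, HCA with selenite 1 against selenite 1). Under depth as a covariate, with replicate block, -0.47 (Gpx4, selenite 1 against control), -0.0617 (Tfap2c, HCA against control), 0.0127 (Gpx4, interaction of HCA and selenite 1), -0.28 (Gpx4, HCA with selenite 0.1 against selenite 0.1). Under without 3 libraries far from the others, -0.0662 (Tfap2c, HCA against control), -0.0578 (Gpx4, HCA with selenite 0.1 against selenite 0.1). Under without 3 libraries far from the others, with replicate block, -0.43 (Tfap2c, HCA against control), 0.0477 (Gpx4, HCA with selenite 1 against HCA with selenite 0.1), -0.49 (Gpx4, HCA with selenite 0.1 against selenite 0.1). Under thinned to one depth without ribosomal RNA type rows, -0.0600 (Tfap2c, HCA with selenite 0.1 against HCA), 0.0639 (Tfap2c, HCA with selenite 1 against HCA with selenite 0.1). Under with replicate block, 0.0663 (Gpx4, HCA with selenite 1 against HCA with selenite 0.1), -0.36 (Gpx4, HCA with selenite 0.1 against selenite 0.1). Without each batch in turn Gpx4, selenite 0.1 against control ranged from -0.113 to 0.916, Tfap2c, selenite 0.1 against control ranged from -0.588 to 0.545, Tfap2c, HCA against control ranged from -0.0942 to 0.986, Tfap2c, HCA with selenite 0.1 against HCA ranged from -0.0575 to 0.285, Tfap2c, HCA with selenite 1 against HCA ranged from -0.110 to 0.123, Gpx4, selenite 1 against selenite 0.1 ranged from -0.626 to 0.281, Gpx4, HCA with selenite 1 against HCA with selenite 0.1 ranged from -0.297 to 0.265, Tfap2c, HCA with selenite 1 against HCA with selenite 0.1 ranged from -0.227 to 0.145, Tfap2c, interaction of HCA and selenite 0.1 ranged from -0.429 to 0.873, Gpx4, HCA with selenite 0.1 against selenite 0.1 ranged from -0.118 to 0.399, Gpx4, HCA with selenite 1 against selenite 1 ranged from -0.348 to 0.489.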

Other observations

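All values here were looked at after the comparisons had been made. In the 3 groups with HCA, which were not tested for equal levels, Aars was at 151 ± 11.9, 151 ± 12.8 and 151 ± 13.8 CPM (SD, n = 6) and Stc2 at 2.35 ± 0.560, 2.19 ± 0.792 and 2.66 ± 0.256, against 78.8 ± 11.4 and 0.596 ± 0.129 in control. Nr4a1 varied widely among HCA libraries, from 3.56 to 15.6 CPM.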
